A study of Caenorhabditis elegans with 3 samples.

How the data were processed

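Fragments crosslinked to FLAG-tagged DCR-1 were sequenced from 3 libraries of whole young adult worms, labelled T1/V1 replicate 1, T1/V1 replicate 2 and T1 replicate 3. The series' design text names both RNases for the experiment, while the label of replicate 3 names RNase T1 alone, and the libraries were grouped by their labels. Per the labels, replicates 1 and 2 carried a custom 3' adapter and replicate 3 the default one, so nuclease and adapter changed together. Nothing in the labels says that the libraries came from separate cultures, so spreads between replicates may be technical.

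The submitters' processing notes name Bowtie2 2.1.0. The genome build and annotation release are not given in the sources used here. Per the file headers and attributes, clusters were called by the authors with a cluster-calling program at an estimated false discovery rate of 5%. Each deposited cluster has a count of T-to-C conversions, a count of reads and a count of all edits, none of them normalised. Each deposited cluster also has the authors' entropy score, which was used only to describe clusters within a list. The library lists hold clusters called for 1 library each. The pooled consensus list holds clusters with reads from at least 2 libraries, and the conservative list holds those with conversions in at least 2 libraries and names another filter on mapping. All 2508 conservative clusters were found in the consensus list with the same position and reads. How many libraries back a pooled cluster is given, but not which, so pooled values are given as the authors' own, with no SD.

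Each cluster was assigned from the authors' annotation to 1 of 14 classes, in the order mitochondrial, miRNA, other noncoding RNA, mRNA parts, intron, antisense, gene flank and intergenic. Gene names came from the lists, from a table of WormBase identifiers and from a table of RefSeq genes of assembly WBcel235, used for names and biotypes and, in 1 alternative, for gene span. Of 2485 sequence names on mRNA parts, 2444 matched that table. Clusters on the mitochondrial genome were assigned to no gene. A cluster over several genes was counted for each.

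A pair of clusters was called overlapping when they shared at least 1 base on the same strand. Chance overlap came from 200 shuffles that kept each cluster's length and chromosome, placed by Python code within the span of the lists on each chromosome. The design named shuffling within genes, which needs an annotation of the build, or else within chromosomes, and the latter was used. It takes no account of where transcripts lie and so can understate chance overlap. Shares carry exact 95% binomial intervals. Classes were compared between libraries by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over all pairs and the 14 classes. Medians were compared by two-sided permutation tests with 100000 resamples, adjusted over all lists, classes and both measures. Gene lists were tested by two-sided Fisher's exact tests against the others of 19983 protein-coding genes, with odds ratios after adding 0.5 to each cell and adjustment over 12 lists. Of the 20 lists fixed before the data were examined, 8 held RNA genes and were described by counts. No test between nucleases was made, since 2 and 1 libraries leave 1 residual degree of freedom and the adapter changed with the nuclease.

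The genes named were set by a rule fixed before the data were examined. It took the 10 miRNA genes with most consensus reads, the 10 other genes with most conservative reads, up to 4 members of each list, the genes let-7, lin-4, lsy-6, rncs-1 and dcr-1, and the 5 strongest genes found with one nuclease treatment and not the other. Positions within miRNA loci were measured on consensus clusters of 55 to 85 nt, since no hairpin coordinates were used. Alternatives covered the overlap rule, the list, the class order, shares of reads or bases, read minimums, backgrounds and left-out replicates.

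The overlap, shuffling, enrichment and permutation code was tested on simulated data. For the gene list comparison, lists of 40 genes were simulated, the enriched ones with 26% of genes hit against 7%. Of these, 93 of 100 enriched lists were recovered at an adjusted p under 0.05, and 2 of 100 unenriched lists were called. Lists of other sizes were not simulated, so the recovery does not carry over to the smaller lists. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.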

Results

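Sites contacted by DCR-1, the single Dicer of Caenorhabditis elegans, were mapped by PAR-CLIP in whole young adult worms of a strain expressing FLAG-tagged DCR-1. In PAR-CLIP, RNA labelled with the photoreactive nucleoside 4-thiouridine is crosslinked to protein by UV light, and crosslinked positions are read as T-to-C conversions in the sequenced fragments. There were 3 libraries. For 2 of them, replicates 1 and 2, the labels name RNases T1 and V1, the latter of which cuts base-paired RNA, and for 1, replicate 3, the label names RNase T1 alone. The values were clusters of overlapping reads, listed for each library and in 2 pooled lists, called consensus and conservative by the authors. T1/V1 replicate 1 had 399 clusters with 7829 reads over 20758 bases, T1/V1 replicate 2 had 377 clusters with 10834 reads over 21771 bases, and T1 replicate 3 had 1304 clusters with 24992 reads over 88081 bases. The median cluster had 7, 9 and 4 reads. The consensus list held 4705 clusters with 92004 reads, and the conservative list held 2508 of these clusters with 78157 reads. All coordinates are those of the authors' lists, whose genome build is not given in the sources used here. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Reads and conversions are the authors' values per cluster.

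The first comparison asked on which RNAs the clusters lay. Clusters annotated as microRNA (miRNA), whose precursors are the classical Dicer substrates, made up 108 of the 4705 consensus clusters but held 29.4% of the consensus reads. This class does not separate precursor from mature miRNA. Exons of protein-coding genes were the most frequent class, with 3084 clusters or 65.5% of the list (interval 64.2% to 66.9%), yet they held 24.3% of the reads. Transfer RNAs held 12% and small nucleolar RNAs, guides of RNA modification, held 9.24% of the reads, in 111 and 105 clusters. A median miRNA cluster had 82.5 reads, against 4 for a coding exon cluster and 3 for a 3' UTR cluster. In the conservative list the miRNA share of reads was 34.6% and that of coding exons 19.1%. In the library lists the order of miRNA and snoRNA was the reverse: miRNA held 22% of the reads in T1/V1 replicate 1, 11% in T1/V1 replicate 2 and 17.3% in T1 replicate 3, and snoRNA held 26.1%, 37.4% and 22%.

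**Figure D1:**
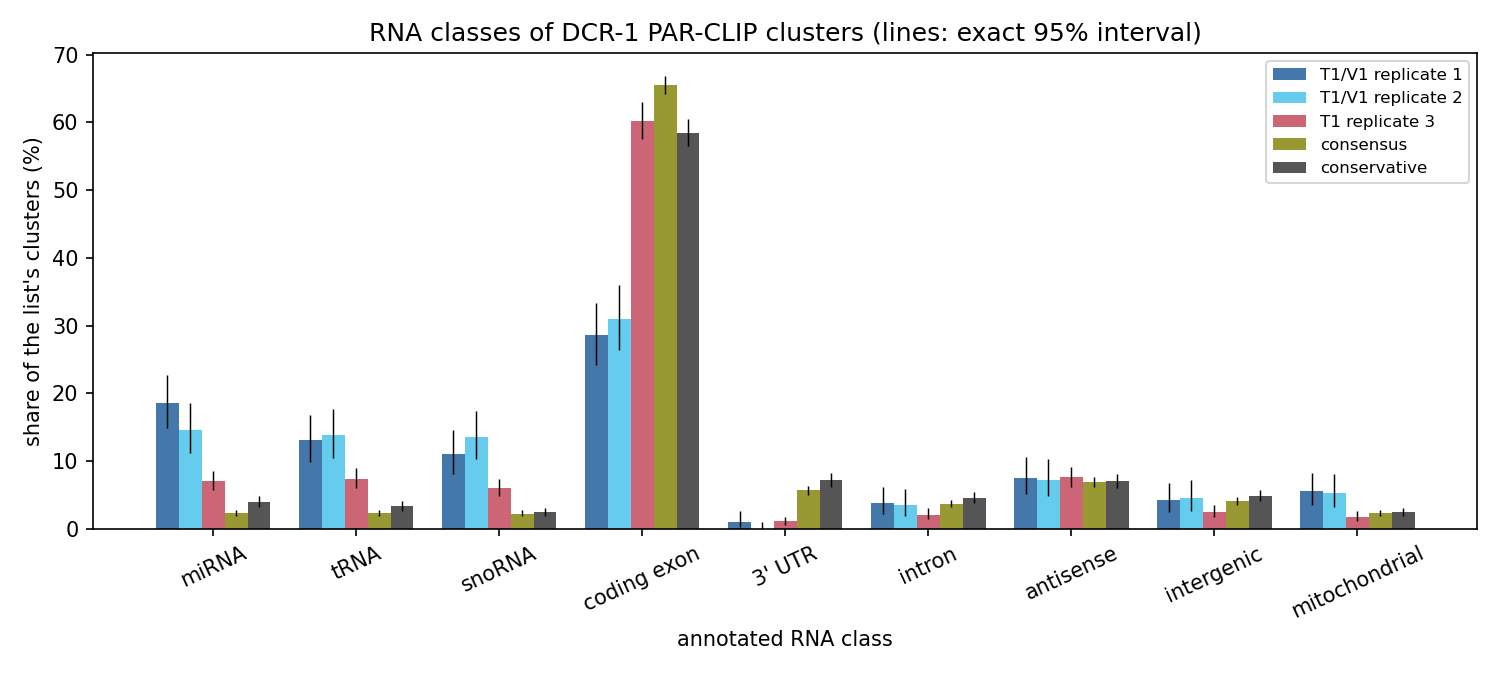
Share of each list's clusters (%, vertical axis) by annotated RNA class (horizontal axis) for the 3 library lists and the 2 pooled lists. The classes shown are a selection that leaves out, among others, gene flank, with 3.19% of the consensus clusters. Bars give the share and lines its exact 95% interval. Coding exons made up 60.3% of the T1 replicate 3 clusters and 65.5% of the consensus clusters, and miRNA made up 18.5% of the T1/V1 replicate 1 clusters.

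Among miRNA genes of the consensus list, the germline and embryonic genes mir-35 and mir-36 and the abundant somatic mir-58 had the clusters with the most reads. In each library mir-58 led, with 212, 148 and 383 reads, and in T1 replicate 3 mir-48 with 335 and mir-71 with 301 followed, ahead of mir-35 with 94. A single consensus cluster on chromosome II, 11537541 to 11537728, spanned both mir-35 and mir-36 and held 1856 reads with 1422 conversions, so the reads of these genes cannot be separated. The mir-58 cluster on chromosome IV, 3233261 to 3233335, held 1854 reads, and the mir-239a cluster on chromosome X, 11792379 to 11792456, held 1579. The genes mir-66, mir-229 and mir-238 followed with 1229, 1147 and 1089 reads. The genes mir-71, mir-60 and mir-54 held 942, 892 and 778 reads. Clusters lay on 97 miRNA genes in the consensus list and on 92 in the conservative list, set beside 260 miRNA genes in a later reference annotation. By library, 62 miRNA genes had a cluster in T1/V1 replicate 1, 45 in T1/V1 replicate 2 and 78 in T1 replicate 3, and 42 genes had one in all 3 libraries.

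Every member of the mir-35, mir-51 and mir-64/mir-229 groups had a consensus cluster, with 8 of 8, 6 of 6 and 4 of 4 genes, whereas the mir-58 and mir-80 family was covered at 4 of 8, the tissue list at 7 of 9 and mirtrons at 3 of 5. The let-7 family and heterochronic genes, timers of larval development, were covered at 6 of 6 genes, led by mir-48 with 622 reads and lin-4 with 452. The let-7 cluster itself, on chromosome X, 14744112 to 14744179, held 215 consensus reads, and library clusters of let-7 held 41 and 33 reads in the T1/V1 replicates and 65 in T1 replicate 3. The lin-4 locus, on chromosome II, 5902233 to 5902295, had no cluster in either T1/V1 list and 66 reads in T1 replicate 3. No list had a cluster on lsy-6, a miRNA of a single neuron type. The mirtron mir-62, which is excised by splicing, had a consensus cluster with 100 conversions, and the mirtrons mir-1020 and mir-1019 held 12 and 4 consensus reads. Of the genes in the tissue list, mir-244 held 653 reads, mir-228 held 427 and the muscle miRNA mir-1 held 277.

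As a share of each list's miRNA reads, the mir-58 and mir-80 family took 19% ± 0.392 (SD, n = 2) in the T1/V1 libraries and 15.3% in the T1 library. The mir-35 family took 5.13% ± 1.05 (SD, n = 2) and 5.49%, a difference smaller than the spread between the T1/V1 replicates. The mir-51 family took 9.36% ± 2.46 (SD, n = 2) and 10.4%, and the let-7 family and heterochronic genes took 14.1% ± 3.82 (SD, n = 2) and 13.1%, again within the spread. In the consensus list the mir-35 family took 13.7% of the miRNA reads, above its interval in each library list, and the mir-58 and mir-80 family took 9.46%, below its interval in each. No test between nucleases was made, since there was 1 T1 library and its adapter also differed.

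**Figure D2:**
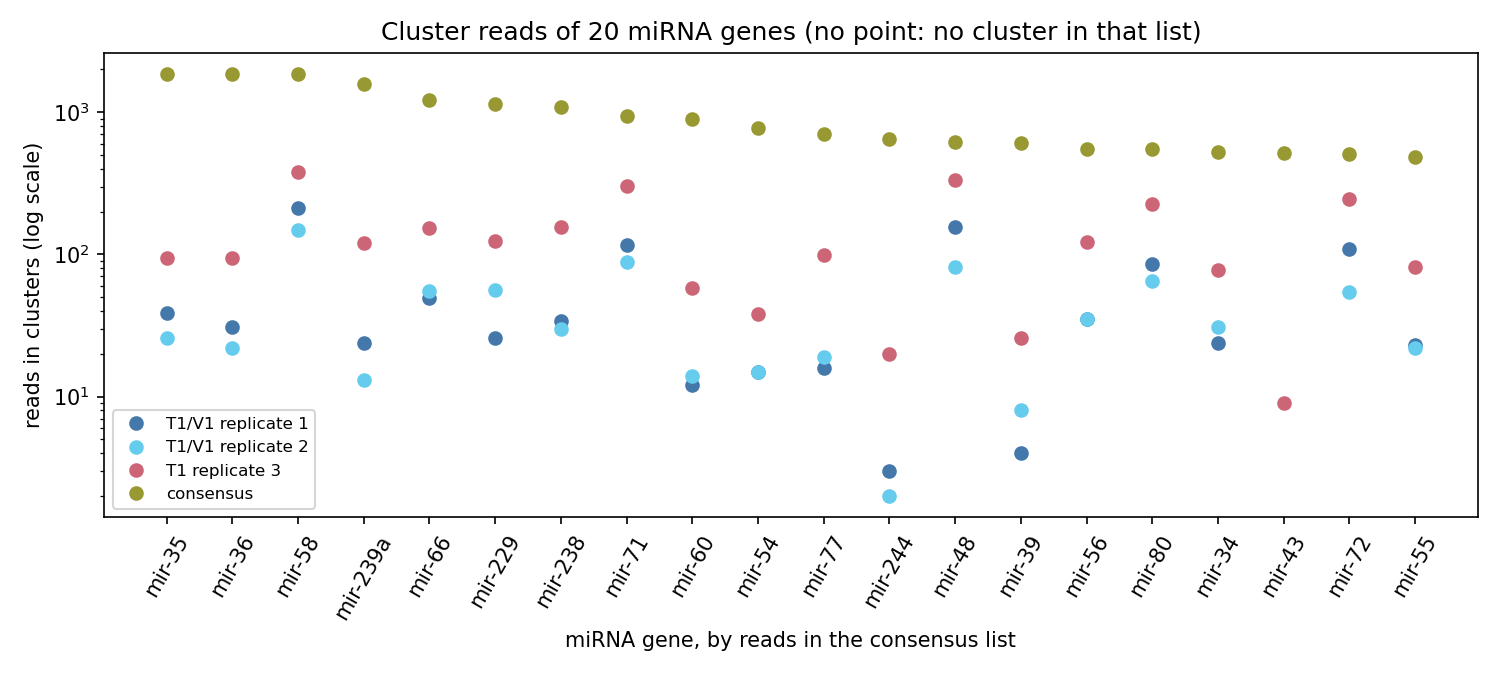
Reads in clusters (log scale, vertical axis) of the 20 miRNA genes with the most consensus reads (horizontal axis), with 1 point per list and no point where a list had no cluster. The consensus value of mir-58 was 1854 reads and its T1 replicate 3 value 383, and mir-35 and mir-36 share 1 consensus cluster of 1856 reads.

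Positions within miRNA loci were counted on 57 consensus miRNA clusters of 55 to 85 nt, whose ends are set by reads and not by hairpin coordinates. Along these, library clusters of at most 35 nt centred in the middle of 3 equal parts in 2 of 37 cases in T1/V1 replicate 1, 0 of 29 in T1/V1 replicate 2 and 3 of 28 in T1 replicate 3. In T1/V1 replicate 1, 18 centred in the 5' part and 17 in the 3' part. In the consensus list the main crosslink position lay in the 5' part of 29 of these 57 clusters, in the middle of 11 and in the 3' part of 17. The median miRNA cluster was 27 nt long in both T1/V1 libraries and 35 nt in the T1 library, and 66 nt in the consensus list. In the consensus list that median of 66 nt was above the 51 nt of coding exon clusters and below the 86 nt of snoRNA clusters, each with p = 1e-05, the smallest that 100000 two-sided permutations can give, across clusters. In the library lists miRNA clusters were instead shorter than coding exon clusters, whose medians were 42, 46 and 51 nt (permutation, adjusted p = 2.22e-05, 6e-05 and 2.22e-05).

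The gene outside the miRNA class with the most conservative reads was the tRNA gene F53B6.t1, with a cluster at chromosome I, 8953160 to 8953189, of 1247 reads, yet it held 3 reads in T1/V1 replicate 2 and had no cluster in the other libraries. The noncoding RNA rncs-1, a long hairpin-forming transcript of the intestine and hypodermis, held 922 reads with 710 conversions in 3 clusters. Its widest cluster lay in exon 2 on chromosome X, 1011976 to 1012268, with 595 reads, and a further one at 1011599 to 1011844 held 318. In the library lists rncs-1 held 5 reads in T1/V1 replicate 2 and 13 in T1 replicate 3, and had no cluster in T1/V1 replicate 1. Consensus clusters of 4 and 21 reads lay on the opposite strand of its clusters of 595 and 318 reads. The noncoding genes F08G2.13 and W01D2.8 held 1024 and 906 reads, and the tRNA genes T07D10.t1, F31E9.t1, K02E11.t1 and K02A4.t2 held 728, 683, 517 and 436. The snoRNA F30H5.4 held 546 consensus reads with 49 conversions and 221, 655 and 438 reads in the library lists, and the Y RNA yrn-1 held 296. The long noncoding RNA tts-1 held 23 reads in 3 clusters.

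**Figure D3:**
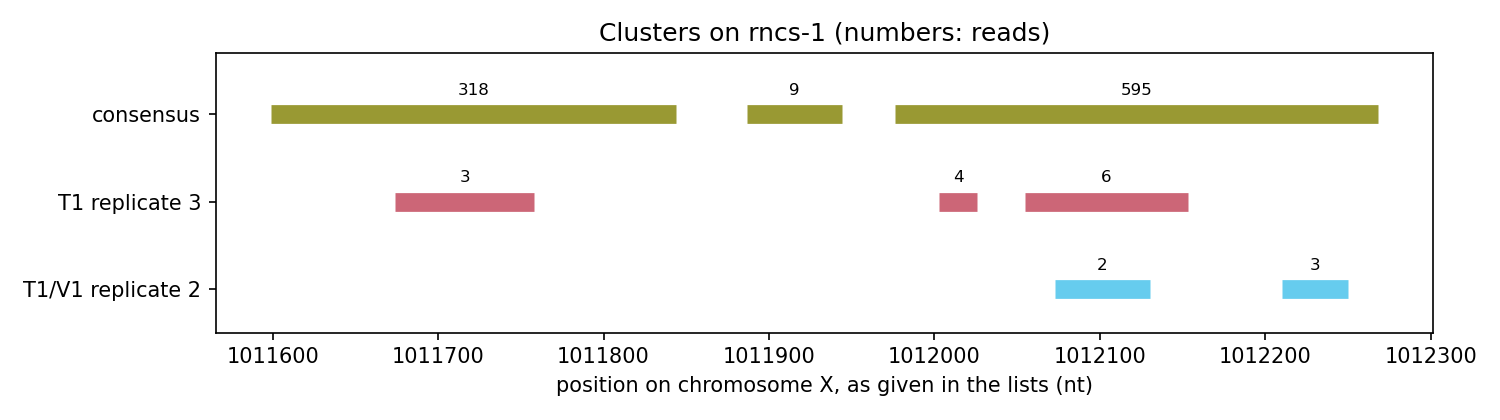
Clusters on rncs-1 along chromosome X (horizontal axis, nt, as given in the lists) in T1/V1 replicate 2, T1 replicate 3 and the consensus list; bars are clusters and numbers their reads. The consensus clusters of 318 and 595 reads cover most of the span in which the library clusters of 2 to 6 reads lie.

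In the consensus list T-to-C conversions made up 48.9% of the edits in miRNA clusters, 28.2% in tRNA clusters, 15.1% in snoRNA clusters, 48.5% in coding exon clusters and 71.5% in 3' UTR clusters. Across clusters, the miRNA median of conversions per 100 edits exceeded the snoRNA median by 38 in the consensus list (two-sided permutation test, p = 1e-05, adjusted p = 2.22e-05). It also exceeded the snoRNA median in T1/V1 replicate 2 and in T1 replicate 3, by 7.16 and 23.8 (permutation, adjusted p = 0.000533 and 2.22e-05), whereas in T1/V1 replicate 1 the difference of 5.56 did not pass (permutation, adjusted p = 0.296). Among clusters above the median read count the difference in T1/V1 replicate 2 no longer passed (3.55, permutation p = 0.191). The miRNA median exceeded the tRNA median by 28.7 in the consensus list and 13.7 in T1 replicate 3 (permutation, adjusted p = 2.22e-05 and 0.000954), but the differences of 1.67 and 3.58 in the T1/V1 replicates did not pass (permutation, adjusted p = 0.738 and 0.417). In all 3 library lists the miRNA median lay below the coding exon median, with differences of -23.3 in T1/V1 replicate 1, -27.8 in T1/V1 replicate 2 and -16.7 in T1 replicate 3 (permutation, adjusted p = 2.22e-05, 2.22e-05 and 0.0109). In the pooled lists it did not differ past the threshold, with 3.40 in the consensus and -3.75 in the conservative list (permutation, adjusted p = 0.104 and 0.262), and among consensus clusters above the median read count the miRNA median was higher, by 8.89 (permutation p = 0.00872). Among clusters above the median read count, the order of the library lists held in T1/V1 replicate 1, with -27.5 (permutation p = 0.00422). It did not hold in T1/V1 replicate 2, where the miRNA median was 3.55 higher (permutation p = 0.419). In T1 replicate 3 it no longer passed (permutation p = 0.445). Every listed cluster held at least 1 conversion, which can raise this measure in clusters of few reads. Coding exon clusters had medians of 2.5, 3 and 3 reads in the library lists.

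The second comparison set protein-coding genes with a conservative cluster, called bound here, against gene lists fixed before the data were examined. Muscle genes, yolk genes and ribosomal protein genes were bound most often. Conservative clusters lay on 15 of 22 muscle genes, 4 of 6 vitellogenin genes and 49 of 78 matched ribosomal protein genes, against 6.61%, 6.66% and 6.46% of the other protein-coding genes. Of the 12 protein-coding lists, 8 had more bound members than the other genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and 0 had fewer.

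The yolk protein genes vit-6 and vit-2 held 637 and 328 conservative reads in 14 and 10 clusters, and vit-5 and vit-1 held 33 and 29 (odds ratio 25.2, Fisher's exact adjusted p = 0.000448). The muscle genes with the most conservative reads were the myosin heavy chain gene unc-54, the twitchin gene unc-22, mlc-3 and the paramyosin gene unc-15, with 207, 107, 48 and 71 consensus reads (odds ratio 29.2, Fisher's exact adjusted p = 1.42e-12). Of the 81 names of the ribosomal protein list, 3 with rla names matched no gene of the name table, and among the matched rpl and rps genes those with the most conservative reads were rps-4, rpl-3 and rps-5, with 155, 160 and 91 consensus reads (odds ratio 24.3, Fisher's exact adjusted p = 4.16e-37). Among germline and oocyte genes, 19 of 40 were bound (Fisher's exact adjusted p = 5.56e-12), with 22 conservative reads on the helicase gene glh-1, 20 on the yolk receptor gene rme-2 and 18 each on gld-1 and chs-1. Intestinal genes were bound at 10 of 20 (Fisher's exact adjusted p = 4.06e-07), led by the protease gene asp-1 with 319 conservative reads and asp-6 with 115. Hypodermal and collagen genes were bound at 12 of 22 (Fisher's exact adjusted p = 7.73e-09), led by col-140 with 156 conservative reads, and all collagen genes at 23 of 156 (adjusted p = 0.000448), led by col-178 with 228. The collagen list shared 13 genes with the hypodermal list, 10 of them bound, and without these, a setting chosen after the data were seen, 13 of the rest, or 9.09%, were bound and the list did not pass (odds ratio 1.46, Fisher's exact adjusted p = 0.314).

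Genes of small RNA pathways were bound at 11 of 36 matched members (odds ratio 6.35, Fisher's exact adjusted p = 2.86e-05). They included dcr-1 itself, with 12 reads in 3 conservative clusters, the nuclear Argonaute gene hrde-1 with 8, and alg-4 and rsd-2 with 7 each. In the consensus list dcr-1 had 8 clusters with 35 reads, the strongest of 11 reads in exon 23 on chromosome III, 8072773 to 8072823, and in the library lists it had 2 clusters with 7 reads in T1 replicate 3 and none in the T1/V1 lists. Sperm genes were bound at 2 of 38, neuronal genes at 1 of 27, histone genes at 8 of 72 and genes targeted by ERGO-1-class small RNAs at 1 of 11 matched members of the 19 given, none of which passed. With log gene span as a term, a setting chosen after the data were seen, the histone list passed (odds ratio 4.87, adjusted p = 5.85e-05 by a logistic fit across genes, which are not independent replicates, against an exact adjusted p = 0.198 without it). Members with conservative reads included ssp-16 with 8 reads, snt-1 with 3, his-59 with 20 and K02E2.6 with 9.

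**Figure D4:**
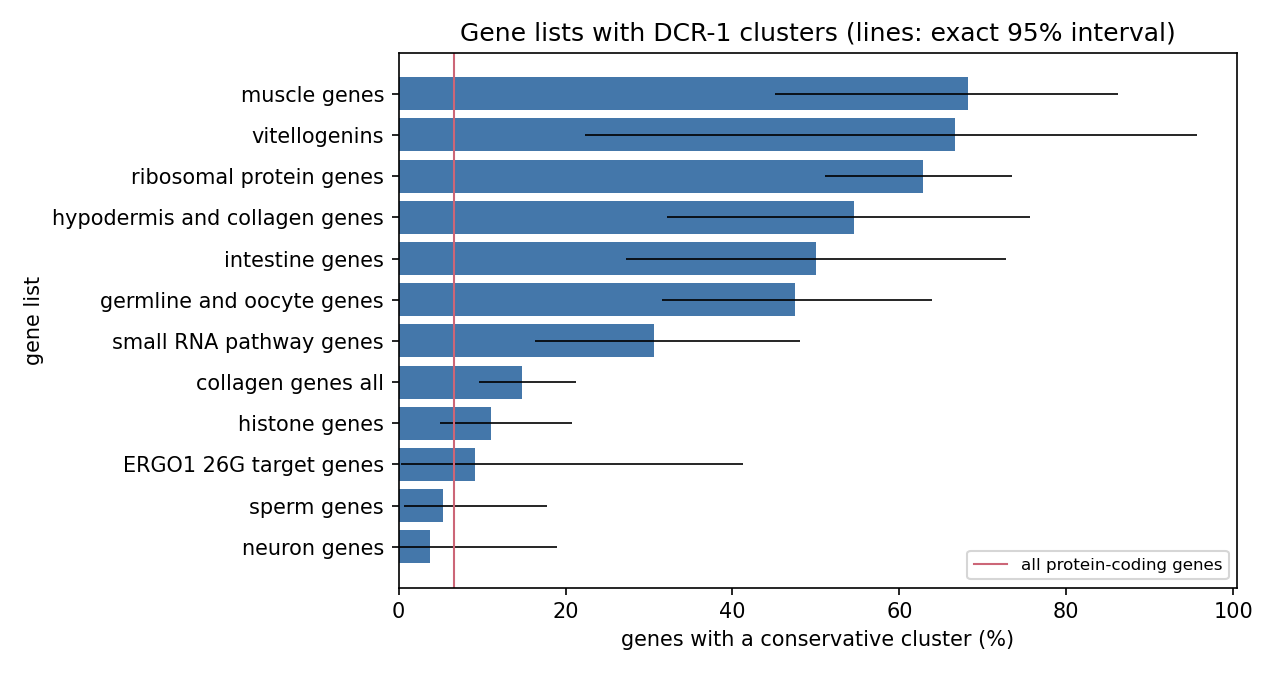
Share of genes with a conservative cluster (%, horizontal axis) in each of the 12 protein-coding gene lists (vertical axis); bars give the share, lines the exact 95% interval and the vertical line the share of all protein-coding genes. Muscle genes stood at 68.2% and ribosomal protein genes at 62.8%, and neuronal genes at 3.70%.

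Expression was not measured in these libraries, so the lists were compared without regard to transcript abundance. With the 2425 genes that had a cluster in at least 1 list as the background, of which 1334 were the bound genes themselves, none of the 8 lists passed by Fisher's exact test, with the smallest adjusted p = 0.0812 for ribosomal protein genes. That background is chosen by the same clusters and does not stand in for expression.

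The third comparison asked whether libraries made with different RNases gave the same clusters. Clusters on miRNA, tRNA and snoRNA genes recurred between libraries more often than clusters on coding exons. They also held more reads. By library, in replicate order, the median coding exon cluster held 2.5, 3 and 3 reads. The medians were 11.5, 12 and 19 for miRNA, 12, 16 and 27 for tRNA and 29.5, 50 and 47.5 for snoRNA. Overlap was higher in the upper part of each list by reads, so RNA class and read count were not separated. Of the T1/V1 replicate 1 clusters, 44.1% (interval 39.2% to 49.1%) overlapped a T1/V1 replicate 2 cluster and 60.7% (55.7% to 65.5%) a T1 replicate 3 cluster. The means were 1.11% and 1.48% in 200 lists shuffled over whole chromosomes, without regard to where transcripts lie. Of the T1/V1 replicate 2 clusters, 63.1% (58.0% to 68.0%) overlapped a T1 replicate 3 cluster. Of the 1304 T1 replicate 3 clusters, 17.6% (15.5% to 19.7%) overlapped a T1/V1 replicate 1 cluster and 17.4% (15.4% to 19.6%) a T1/V1 replicate 2 cluster. By class, 45 of 74 miRNA clusters of T1/V1 replicate 1 and 9 of its 114 coding exon clusters recurred in T1/V1 replicate 2, and 72 of 74 and 31 of 114 recurred in T1 replicate 3. In the other direction, 62 and 43 of 91 miRNA clusters and 30 and 32 of 786 coding exon clusters of T1 replicate 3 recurred in the T1/V1 replicates. Of the 52 tRNA and 44 snoRNA clusters of T1/V1 replicate 1, 46 and 36 recurred in T1 replicate 3, and of the 96 tRNA and 78 snoRNA clusters of T1 replicate 3, 45 and 37 recurred in T1/V1 replicate 1. Read counts of clusters shared by 2 libraries correlated across clusters, which are not independent replicates, with Spearman's rho of 0.857, 0.878 and 0.839 over 170, 211 and 206 clusters.

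Coding exons made up 29.8% ± 1.74 (SD, n = 2) of the T1/V1 clusters and 60.3% of the T1 clusters, and miRNA 16.6% ± 2.8 (SD, n = 2) and 6.98%. By Fisher's exact test, which compares these libraries and not the nucleases, 5 of 14 classes differed between T1/V1 replicate 1 and the T1 library and 6 of 14 between T1/V1 replicate 2 and the T1 library at an adjusted p under 0.05, and 0 between the T1/V1 replicates. The lists differed in length, however. With the 377 clusters of most reads taken from each library, coding exons made up 26%, 31% and 26.5%. In each pair 0 of 14 classes differed. Those clusters reached down to 2 reads in each T1/V1 library and to 10 in the T1 library, so that setting did not match them for reads. At an unadjusted p under 0.05, that setting gave 1 class, snoRNA, between T1/V1 replicate 1 and the T1 library.

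Of 1092 genes with a cluster in any library, 135 had one in all 3, among them 42 miRNA genes, 35 tRNA genes and 30 snoRNA genes. In both T1/V1 libraries and not in the T1 library were 11 genes, none of them miRNA genes. The strongest were introns of B0524.1, with 75 and 39 reads, and of tir-1, with 61 and 24. The collagen gene col-20 followed with 29 and 13, and then the snoRNA genes C16D9.11 and K02C4.8. Of these, B0524.1, tir-1 and C16D9.11 had no cluster in either pooled list, whereas col-20 and K02C4.8 had clusters in both. In the T1 library and neither T1/V1 library were 660 genes, of which 560 had their clusters in mRNA parts. The strongest were the snoRNA Y37E3.20 with 123 reads, the tRNA genes T04D3.t1 and C44B7.t1, the latter with 102, the ribosomal protein gene rplp-0 with 88 and the tRNA gene ZK678.t2 with 82.

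Most clusters of the pooled lists lay outside the library clusters. In the other direction, 68.4% of the T1/V1 replicate 1 clusters, 70.6% of T1/V1 replicate 2 and 72.2% of T1 replicate 3 overlapped a consensus cluster. Of the consensus clusters, 3723 overlapped no library cluster, 692 overlapped clusters of 1 library, 140 of 2 and 150 of all 3. The miRNA class was found in all 3 libraries at 41 of 108 consensus clusters, and coding exons at 10 of 3084. Of the 266 consensus clusters in 3' UTRs, 258 overlapped no library cluster. Of the 2508 conservative clusters, on which the gene list comparison rests, 1730 overlapped no library cluster and 135 were found in all 3 libraries. Among the 1467 conservative coding exon clusters, 1029 overlapped no library cluster. Pooled reads fell below the sum of the library reads at 52 of 109 loci where clusters of all 3 lay inside the pooled one, and exceeded it at 57.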

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

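These counts were chosen after the repeat annotation of the lists, which no comparison of the report used, had been seen. Among nuclear consensus clusters, 45 lay on annotated transposon repeats, with 625 reads, and the library lists held 2 such clusters in T1/V1 replicate 1, 0 in T1/V1 replicate 2 and 2 in T1 replicate 3. The retrotransposon CER10 had 4 consensus clusters on chromosome X with 172 reads and 179 conversions among 280 edits, the strongest at 9191856 to 9191893 with 89 reads, and no cluster in any library list. With no control sample used here, both values were picked out only because they are counts above 0 in an annotation that no comparison used. Neither was tested against the library lists, which held 377, 357 and 1281 nuclear clusters to the 4598 of the consensus list. No explanation, technical or biological, was tested.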

How the results depend on the processing

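No paired analysis was possible because the nuclease groups share no replicate number and hold 2 and 1 libraries. The equal numbers of clusters, the 10-read minimum, gene span, the position of short clusters within pooled miRNA clusters, in 3 parts and in 5, the nuclear clusters alone and the collagen list without shared genes were chosen after the data were seen. A minimum of 50% of the cluster inside the hairpin was not run, since no hairpin coordinates were used. A tested result was counted as the same when its direction and side of the threshold held, whatever its size. A gene list whose odds ratio crossed 1 also counted as the same where neither result passed. This occurred for the ERGO-1, sperm and neuronal lists, and such changes are not among the turned directions given next. A count was the same when it stayed within 1.5 times, and a share when it stayed within its interval or 1 SD between replicates. Of the other settings fixed in advance, 66 left the result the same and 33 moved it, 10 ended a call, 1 gained one and 2 turned a direction, and of those chosen later 13 left it the same and 6 moved it, 1 gained a call, 1 ended one and 1 turned a direction. Except where stated, the cause was not tested. With 1 library left out, the T1 minus T1/V1 coding exon share ranged from 29.2 to 31.7 points, consensus clusters found in every remaining list from 155 to 220 against 150, conservative ones from 136 to 196 against 135, and miRNA genes in any library from 65 to 80 against 81.

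At or above the median reads, the lists held 211, 189 and 653 clusters by construction. In the upper part of each list by reads, overlap of T1/V1 replicate 1 with T1/V1 replicate 2 was 63%, and overlap with T1 replicate 3 was 84.4% for T1/V1 replicate 1 and 89.4% for T1/V1 replicate 2. There the consensus shares were 3.77% miRNA, 3.73% tRNA, 3.69% snoRNA, 63.8% coding exon and 4.17% 3' UTR, and the coding exon gap was 36.4 points. With reciprocal overlap of 50%, overlap with the T1 library was 46.1% and 46.9%. In the conservative list the shares were 3.99% miRNA, 3.31% tRNA, 58.5% coding exon and 7.14% 3' UTR. As shares of reads they were 29.4%, 12% for tRNA, 9.24% snoRNA, 24.3% coding exon and 1.27% 3' UTR, with a gap of 12.7 points, and as shares of bases 3.58% snoRNA, 69.0% coding exon and 3.71% 3' UTR, with a gap of 32.7 points. With mRNA parts placed before noncoding RNA, by construction, miRNA fell to 1.79%, tRNA to 1.72% and snoRNA to 0.893%.

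The gap was 21.6 points at 10 reads or more and -1.99 with equal numbers of clusters, where 0 classes differed between any libraries. The latter setting shortened the T1 list to clusters of at least 10 reads, against at least 2 in each T1/V1 list. Against genes with a cluster in at least 1 list, odds ratios were 2.70 for small RNA pathway genes, 7.38 for vitellogenins, 2.93 for germline, 3.65 for muscle, 4.12 for hypodermal, 2.47 for intestinal, 2.01 for ribosomal protein and 1.24 for collagen genes, none past the threshold, with fewer genes in the comparison by construction. With gene span as a term, the histone odds ratio was 4.87, and without the genes of the hypodermal list, the collagen odds ratio was 1.46. Above the median reads, the miRNA minus coding exon median of conversions per 100 edits was 3.55 in T1/V1 replicate 2, -3.65 in T1 replicate 3, 8.89 in the consensus (permutation p = 0.00872, a call gained in the direction opposite to the library lists) and 3.34 in the conservative list, and the miRNA minus snoRNA median in T1/V1 replicate 2 was 3.55 (permutation p = 0.191), which ended that call. Summed per gene, Spearman's rho was 0.814 between the T1/V1 replicates and 0.848 between T1/V1 replicate 1 and T1 replicate 3. In the middle of 5 parts, 0% of short miRNA clusters centred in each library. Without mitochondrial clusters, 54 clusters had a partner on the other strand. The 1 T1 library and a median of 4 to 9 reads per library cluster limit all comparisons between libraries.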

Other observations

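The tests of pooled against library reads, the minimum of 10 reads and the equal numbers of clusters as settings, the split by nuclear genome, the counts of loci in place of clusters and the test of abundant nuclear loci were chosen only after the results were seen.

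Some of the strongest conversion signals lay outside annotated small structured RNAs, at loci chosen after their values were seen. A 26 nt cluster on chromosome X, 14882863 to 14882888, antisense to a CELE45 repeat, held 322 reads with 535 conversions and had no library cluster. A cluster antisense to exon 3 of F43E2.6 on chromosome II, 7367505 to 7367576, held 660 reads with 523 conversions, and a cluster of 101 reads lay on the sense strand at 7367506 to 7367575. A cluster antisense to an intron of ZK185.2 on chromosome IV, 4538697 to 4538911, held 718 reads, with 30, 74 and 150 reads in the library lists. In coding exons, R102.3 held a 33 nt cluster of 233 reads, F55A12.5 a 42 nt cluster of 130 reads with 187 conversions, col-178 a 71 nt cluster of 228 reads and emb-9, a basement membrane collagen gene, a 70 nt cluster of 111 reads, and in the library lists these 4 were found in T1 replicate 3 alone, with 57, 25, 26 and 12 reads. A 48 nt coding exon cluster of tag-319, with 71 reads and 167 conversions, was found in no library list.

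Coding exon clusters were more frequent in the T1 library. A minimum of 10 reads left the T1 share at 26.8% (interval 22.5% to 31.6%), above 5.95% and 4.55% in the T1/V1 libraries, an outcome set, before that result was seen, to argue against a surplus of low-read clusters. The minimum left 103 coding exon clusters in the T1 list, against 10 and 8. The outcome set in advance was thus met, with a limit. The minimum kept 384 clusters of the T1 list against 168 and 176, and so reached further down that list. With equal numbers of clusters, a setting chosen later, the T1 share was 26.5% at 377 clusters and 15.2% at 250. At each number it lay within the intervals of both T1/V1 libraries. Those T1 clusters held at least 10 and 21 reads, against at least 2 and 4 in each T1/V1 library. The equal numbers were thus not matched for reads and cannot decide whether low-read clusters made the gap. Effects of the nuclease, of the adapter and of a surplus of low-read clusters could not be told apart, since there was 1 T1 library.

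Pooled reads were not the sum of the library lists. At 109 loci where clusters of all 3 libraries lay inside the pooled one, pooled reads fell below the sum at 52, or 47.7% (interval 38.1% to 57.5%), and exceeded it at 57, or 52.3% (42.5% to 61.9%), so the pooled lists neither hold every read counted in the library lists nor hold those reads alone. The median ratio of pooled reads to the sum was 2.88 for 41 miRNA clusters and 0.578 for 30 snoRNA clusters. Pooled reads exceeded the sum at 46 of 60 loci where the pooled cluster was wider than the library clusters together and at 11 of 49 with the same extent, but a cluster is wider because it holds further reads, so these counts test no cause. Why pooled reads lay above or below the sum stays open, and no biological explanation was tested.

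Clusters lay on both strands of one locus more often than in lists shuffled over whole chromosomes. That placement takes no account of where transcripts lie, so it can understate chance and cannot decide whether the count exceeds it. The count was 131 consensus clusters, against at most 95 in 200 shuffled lists, and 77 of them were mitochondrial; among nuclear clusters it was 54, against at most 30. Of the 200 clusters with most reads, 6.5% had a partner on the other strand, above the interval of the rest (2.17% to 3.13%). With clusters within 1000 nt counted as 1 locus, the shares were 4.62% of 173 loci and 0.676% of 3253. This was the outcome predicted for reads on the wrong strand at abundant loci, but 8 of the 13 clusters with a partner were mitochondrial. It cannot decide that explanation, because it takes no account of conversions, of which every consensus cluster held at least 1. Nuclear clusters of at least 100 reads were also counted as loci. A partner was found at 0 of 95 miRNA, tRNA, snoRNA and snRNA loci and 3 of 39 others (Fisher's exact p = 0.0233). The others include clusters classed as antisense, which lie opposite an annotated gene, as at F43E2.6 and Y54E10A.5. This comparison, on 3 loci, therefore cannot decide whether reads lay on the wrong strand, though at the 95 structured RNA loci high read counts came with no partner. The 3 loci were F43E2.6, rncs-1 and Y54E10A.5. Their partner clusters held 59 conversions at F43E2.6, 14 at Y54E10A.5, and 2 and 1 at rncs-1. Transcription of both strands there was not tested.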
